A study of Mus musculus with 16 samples.

How the data were processed

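RNA from sorted mouse bone marrow cells was measured on 16 Affymetrix mouse expression arrays. Total RNA was extracted with a microRNeasy kit, and biotinylated cRNA was made from 4000 to 7000 cells per sample, per the labels. The deposited values are summarised probe set intensities on a linear scale (unit: intensity) for 45101 probe sets. The summary method, the background correction and the normalization between arrays are not given in the sources used here. The highest value is 32952, and the quantiles of the arrays are close but not equal. Depth in the sense of a read count does not apply to arrays, and the number of arrays per group limits the precision.

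The arrays fall into 6 groups by their labels. There are 3 arrays of hematopoietic stem cells (HSC) from young mice of 9 to 12 weeks, 3 from old mice of 24 months, 3 from mid-aged wild-type mice of 32 weeks and 3 from mid-aged mitochondrial mutator mice of 32 weeks. Mutator mice carry a proofreading-deficient mitochondrial DNA polymerase (Polg) on both alleles and accumulate mutations in mitochondrial DNA. The remaining arrays are common lymphoid progenitors (CLP) from wild-type mice of 8 to 12 weeks, 2 sorted as Ly6D-positive and 2 as Ly6D-negative. All samples are labelled female and C57Bl6, and the replicates are labelled biological.

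Values were used as deposited and transformed to log2(intensity + 16). Of the probe sets, 34958 carry 1 gene symbol, 932 carry several, 9211 carry none and 64 are controls. Each of 18194 genes was represented by its probe set with the highest mean over the arrays of the fit. A gene entered a test if that probe set lay above the 40th percentile of its array on at least 3 of the 12 HSC arrays, which kept 13492 genes, or on at least 2 of all 16 arrays, which kept 14343 genes. A group mean at or below that percentile is called background, and the size of a log2 change from or to it depends on the pseudocount. No column of values was left out.

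Group means were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with defaults), and p-values were adjusted by the Benjamini-Hochberg method over the genes tested. A gene is described as higher or lower, or as risen or fallen, when its adjusted p was under 0.05. The HSC comparisons came from the fit of 12 arrays and share 1 estimate of the spread. The 2 comparisons with CLP came from the fit of all 16 arrays. The difference of effects is the change from mid-aged wild type to mutator minus the change from young to old, tested as 1 contrast. Fold changes are given as log2 values with the standard error (SE) from limma, and intensities as mean ± SD over the arrays of a group.

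Genes are named by a fixed rule. In each comparison it takes the 10 largest changes in each direction among genes past the threshold whose 2 groups of arrays do not overlap, leaving out unnamed and provisional gene symbols. Where none passed, it takes the 5 genes with the smallest p in each direction as values only. It adds up to 4 members of each gene list past the threshold, or the 2 with the smallest p as values, and always Polg, Ly6d, Il7r, Flt3, Kit, Slamf1, Cd34 and Xist. The condition on overlap was not applied to the difference of effects, which has 4 groups. Microarray control transcripts and genes of other cell types named for the checks fall outside this rule and were chosen after their values were seen.

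The study's question was approached with 31 gene lists written from general knowledge, of which 542 of 604 symbols matched a gene. They cover HSC identity, genes known to rise in aged HSC, blood lineages, heme and iron, mitochondrial genes and metabolism, stress responses, p53 targets, cell cycle, DNA repair, chromatin, handling, other cell types of the marrow and sex-linked transcripts. The list of genes known to rise in aged HSC may rest in part on these arrays, so in old against young HSC it is not independent evidence. Lists with at least 3 tested members were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry. Adjusted p-values for lists are over all lists of 1 comparison. Sets of genes raised or lowered with age were defined on the 6 young and old arrays alone and tested on the 6 mid-aged arrays alone. The position of each mid-aged array along the direction from young to old was compared by an exact two-sided permutation test. The comparisons, tests, gene lists, rule for named genes and the first set of alternatives were chosen before the data were examined.

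The alternatives were quantile normalization, median centring, no filter on dim genes, a filter at the 60th percentile, the mean of all probe sets of a gene, every probe set, eBayes with trend and robust settings, array weights, pseudocounts of 1 and 64, the replicate number as a block, leaving out each array, fitting only the groups compared, and fitting all 16 arrays. For the age sets the 100 genes of smallest p were tried. A further 4 alternatives were added after the data were seen, namely leaving out genes on X and Y, the hybridisation controls as a block, leaving out the 2 mid-aged arrays with high hybridisation controls (mutator replicate 1 and wild-type replicate 1), and counting young replicates 2 and 3 as 1.

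The tests were checked on simulated data with 200 changed genes and 5 runs. With equal spread in all groups, between 3.91% and 7.75% of the calls were unchanged genes. With the typical spread of each group as measured, this share was 39.9% for mutator against mid-aged wild-type HSC and 43.7% for Ly6D-positive against Ly6D-negative CLP. It was 17.2% for mid-aged wild type against young, 15.1% for old against mid-aged wild type, 6.91% for the difference of effects, 3.49% for mutator against young, 2.50% for mutator against old, 3.90% for CLP against young HSC and 0% for old against young. With the SD of each gene in each group taken as true, which overstates differences in spread, the share was 59.2% for mutator against mid-aged wild type, 79.6% between the CLP groups, 41.1% for mid-aged wild type against young and 45.6% for old against mid-aged wild type. It was then 27.9% for the difference of effects, 19.0% for mutator against young, 21.1% for mutator against old, 37.6% for CLP against young HSC and 2.67% for old against young. Under the typical spread a 2-fold change was called for 56.7% of genes in mutator against mid-aged wild type, 53.1% in old against young, 34.0% between the CLP groups and 14.0% in the difference of effects.

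The knock-in at Polg is a point mutation, so expression at its probe sets does not check the genotype. Of the mitochondrially encoded genes, 1 was represented by a named probe set. Probe sets with no gene symbol or with several were not used here.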

Results

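Gene expression was measured on 16 arrays of sorted mouse bone marrow cells. They comprise 3 arrays each of young HSC, old HSC, mid-aged wild-type HSC and mid-aged mutator HSC, and 2 arrays each of Ly6D-positive and Ly6D-negative CLP. HSC are the multipotent stem cells of the blood, and CLP are progenitors that give rise to lymphocytes, with Ly6D marking those biased to the B lineage. The median intensity of the arrays lay between 24.6 and 29.8 and the mean intensity between 211 and 264. The series asks whether the premature blood ageing of mutator mice resembles, at the level of HSC transcripts, the ageing of normal HSC.

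Ly6d and Il7r followed the labels of the groups. Ly6d reached 1442 ± 447 (SD, n = 2) in Ly6D-positive CLP, 38.8 ± 22.4 in Ly6D-negative CLP and 16.7 ± 2.67 (n = 3) in young HSC. Il7r, the receptor chain for interleukin 7, was at 3673 ± 363 and 2507 ± 487 in the 2 CLP groups and at 13.8 ± 1.79 in young HSC. Kit, the stem cell factor receptor, was at 3193 ± 695 in young HSC, 4188 ± 1083 in old HSC, 1024 ± 470 in mid-aged wild-type HSC and 1471 ± 501 in mutator HSC. Polg itself (chromosome 7) gave 167 ± 15.998 in young, 159.6 ± 4.20 in old, 143 ± 26.4 in mid-aged wild-type and 100.3 ± 30.6 in mutator HSC.

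Some differences between arrays did not follow the labels. Xist, which is expressed from the inactive X of female cells, was between 9.12 and 16.8 in mid-aged wild-type replicate 3 and in all 4 CLP arrays, against 3507 to 11022 in the other 11 arrays. Eif2s3y on the Y chromosome was between 423 and 758 in the same 5 arrays and between 6.85 and 12.7 elsewhere, although all samples are labelled female. The log2 ratio of 3 prime to 5 prime actin signal was 2.20 to 2.27 in old, 2.39 to 2.61 in young and 4.24 to 5.26 in the 6 mid-aged arrays. Over the 12 HSC arrays the leading principal component held 56.0% of the variance and separated the mid-aged arrays (13.4 to 68.7) from the young and old arrays (-45.9 to -32.9). The median SD of a gene between replicates was 0.127 log2 units in young, 0.135 in old, 0.238 in mutator and 0.343 in mid-aged wild-type HSC.

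**Figure D1:**
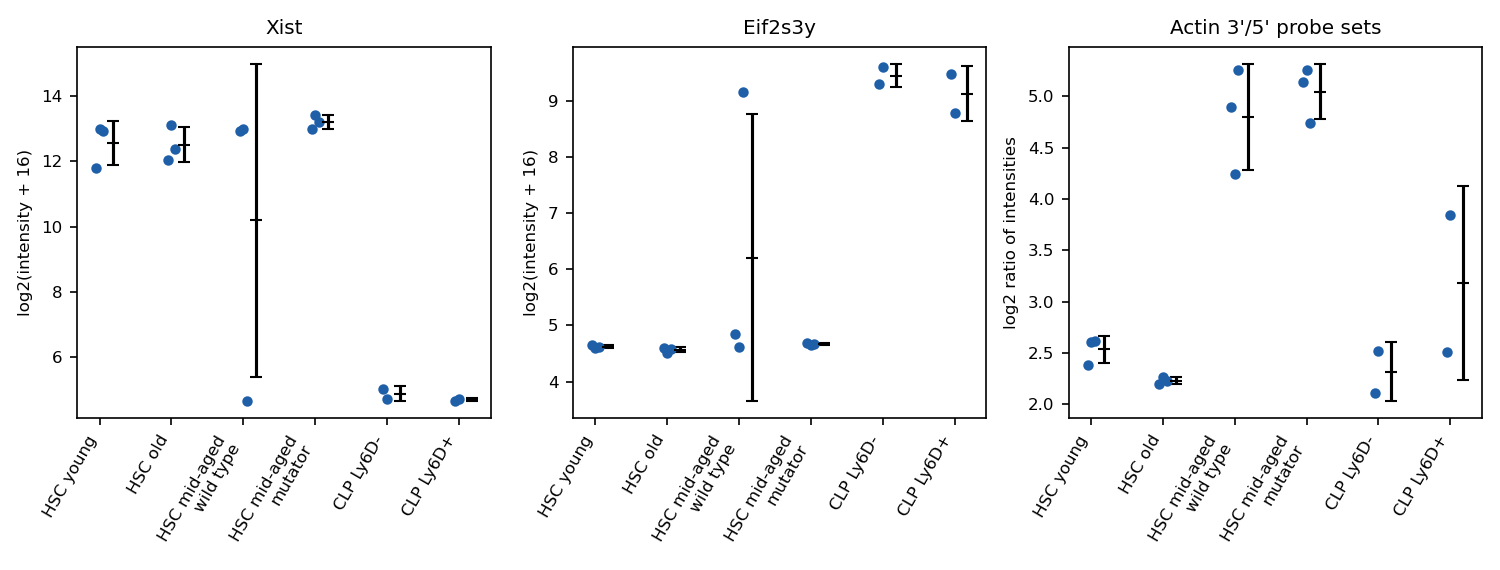
Values per array (dots) in the 6 groups for Xist and Eif2s3y, as log2(intensity + 16), and for the log2 ratio of 3 prime to 5 prime actin signal. The Y-linked signal appears in mid-aged wild-type replicate 3 and in the 4 CLP arrays, and the actin ratio of the mid-aged HSC arrays (4.24 to 5.26) lies above that of young and old HSC.

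Old and young HSC were compared to describe normal ageing. Ctse (chromosome 1), the protease cathepsin E, rose from an intensity of 340.0 ± 17.7 to 4559.8 ± 317 in old HSC (log2 change 3.68 ± 0.246, SE, n = 3 and 3, adjusted p 3.32e-05). Sbspon (chromosome 1), which encodes a secreted matrix protein, rose from background (17.0 ± 3.34) to 767 ± 259 (adjusted p 2.81e-04), and its log2 change of 4.51 ± 0.442 was 5.37 and 3.30 with pseudocounts of 1 and 64. The smallest adjusted p belonged to the sulfotransferase gene Sult1a1 (chromosome 7), which rose from 339 ± 26.6 to 2485 ± 218 (log2 change 2.81 ± 0.140, adjusted p 3.78e-06). In the other direction Plac8 (chromosome 5) fell from 2602 ± 780 to 501 ± 254 (log2 change -2.44 ± 0.381, adjusted p 0.00749), and Camk1d (chromosome 2), a calcium-dependent kinase, fell from 114 ± 19.8 to 25.4 ± 3.24 (log2 change -1.64 ± 0.157, adjusted p 2.63e-04). Each of these genes stayed past the threshold with any 1 of the 6 arrays left out.

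In all, 180 of 13492 genes passed the threshold, 145 higher and 35 lower in old HSC, and 144 of them changed at least 2-fold. The young and old arrays did not overlap for 27.1% of genes, where chance gives 10% for 3 against 3. Further increases were in Eya4 (log2 change 3.93 ± 0.416), Tdrd9 (3.85 ± 0.321), the phospholipid scramblase gene Plscr2 (3.69 ± 0.332), Wwtr1 (3.35 ± 0.526), a coactivator of the Hippo pathway, and the chemokine receptor gene Cxcr4 (3.34 ± 0.395). Clca3a1 (3.26 ± 0.305) and Gpr183 (3.18 ± 0.310), a receptor for oxysterols, rose too, as did Fap (3.59 ± 0.592), which lost its call without old replicate 1 or young replicate 1 (3.34 to 3.79 with 1 array left out). Eya4 and Gpr183 were at background in young HSC, and their log2 changes were 2.73 and 2.04 with a pseudocount of 64. Falls were smaller, as in Ebi3 (-1.42 ± 0.222) and Ncf1 (-1.35 ± 0.157), a subunit of the phagocyte oxidase. Cdca8 (-1.59 ± 0.278), Pclaf (-1.55 ± 0.292) and Cdca5 (-1.38 ± 0.260), genes of proliferating cells, fell as well. Each lost its call without old replicate 1 or 2 or young replicate 2 or 3, and Pclaf also without young replicate 1, with log2 changes between -1.86 and -1.12. The count was 86 without old replicate 1 and 114 without young replicate 1, with the other 4 leave-one-out fits in between. It was 92 with young replicates 2 and 3 counted as 1, 1057 when the 6 young and old arrays were fitted alone and 1883 with array weights. In the common fit the wider spread of the mid-aged arrays enters the error of each comparison.

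Genes known to rise in aged HSC rose here too, although this list is not independent evidence. Of its 37 tested members 23 rose and none fell, 14 did not pass, and 33 rose when adjusted over the list alone (median log2 change 1.98, camera adjusted p 2.51e-68). The call held with an estimated correlation (adjusted p 0.00404). Members included Nupr1 (2.93 ± 0.222), a stress-response regulator, Tm4sf1 (2.91 ± 0.212), Ptprk (2.22 ± 0.192) and Selp (2.89 ± 0.260), which encodes the platelet adhesion molecule P-selectin and went from 152 ± 43.8 to 1208 ± 117.

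**Figure D2:**
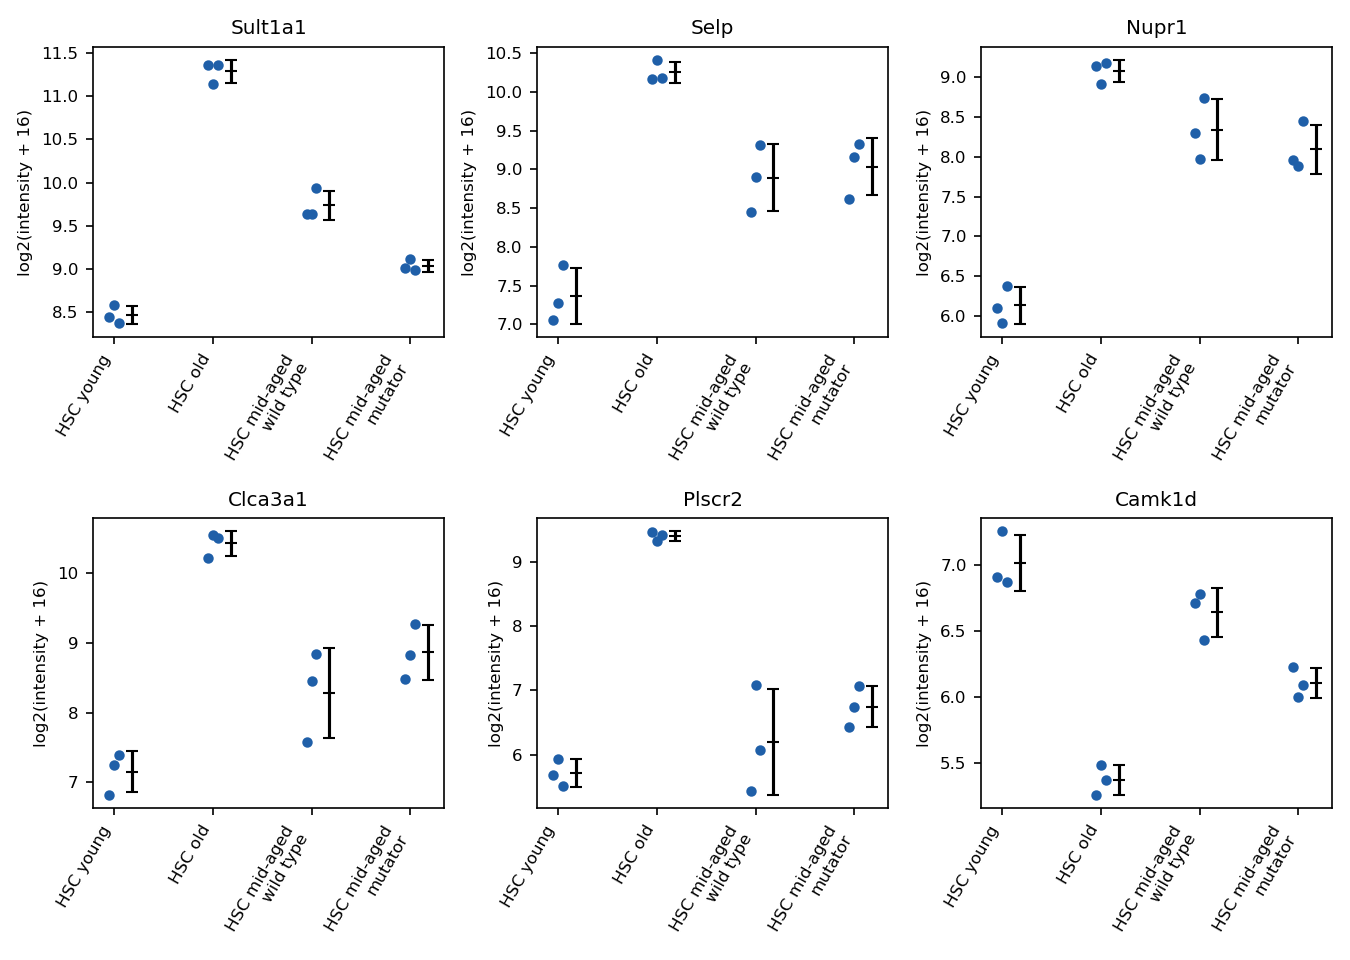
Expression of Sult1a1, Selp, Nupr1, Clca3a1, Plscr2 and Camk1d in young, old, mid-aged wild-type and mutator HSC, as log2(intensity + 16). Dots are arrays and bars the mean ± SD of 3 arrays, and the old arrays lie above the young arrays for each gene but Camk1d, which is lower in old HSC.

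HSC identity and megakaryocyte lists were also called higher in old HSC. RNA quality is confounded with age in every change between these groups, since log2 3 prime to 5 prime ratios of actin (2.20 to 2.27 in old, 2.39 to 2.61 in young) and Gapdh (2.93 to 2.97, 3.15 to 3.32) did not overlap. Of 24 HSC identity genes 3 rose, none fell and 21 did not pass, with 6 higher and 1 lower adjusted over the list alone (median 0.39, adjusted p 1.03e-07). With an estimated correlation this list had an adjusted p of 0.0717. The risen members were Hoxb5 (1.03 ± 0.188), Slamf1 (1.07 ± 0.205), which encodes the stem cell marker CD150, and Procr (0.78 ± 0.145). Of 18 megakaryocyte and platelet genes 3 rose and none fell, against 6 and 0 adjusted over the list alone (median 0.34, adjusted p 1.19e-05, estimated-correlation adjusted p 0.0717). They were Selp, the platelet integrin gene Itgb3 (1.63 ± 0.340) and Clec1b (0.89 ± 0.165). Calls for Slamf1, Procr, Itgb3 and Clec1b were lost in all 6 fits that left out 1 array, and that for Hoxb5 in each but the one without old replicate 2, with log2 changes between 0.73 and 1.78 throughout.

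Among stress and checkpoint genes, 2 of 19 p53 targets rose, Plk2 (2.54 ± 0.330) and Perp (1.505 ± 0.262), and none fell over all genes or adjusted over the list alone. The list had a median of 0.30 and an adjusted p of 3.34e-04, with an estimated-correlation adjusted p of 0.0967. Immediate early genes of cell handling had no call over all genes and 1 adjusted over the list alone (Socs3 2.93, adjusted p over all genes 0.0575), yet 22 of 23 were positive (median 0.47, adjusted p 9.36e-04, estimated-correlation adjusted p 0.551). The call for that list was lost without old replicate 1, where its median was 0.0183, and without young replicate 3, where it was 0.184. Perp lost its call without old replicate 1 or 3 or young replicate 2 or 3 (1.31 to 1.69).

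The cell-cycle list was called lower in old HSC. Of 29 members 27 had a negative change (median -0.98, adjusted p 4.67e-16, estimated-correlation adjusted p 0.0717). Over all genes 1 fell and none rose, the replication licensing gene Mcm5 (-0.99 ± 0.204), whose call was lost in all 6 leave-one-out fits (-1.05 to -0.90). Adjusted over the list alone 16 fell and 1 rose. Of 17 DNA repair genes none passed over all genes and 3 fell adjusted over the list alone (median -0.28, adjusted p 3.12e-04, estimated-correlation adjusted p 0.0717), with Lig1 at -0.93 (adjusted p 0.050026). Neutrophil list means were 5.08 to 6.91 in old and 6.50 to 8.45 in young arrays. An effect of age on cell-cycle genes therefore cannot be told apart from neutrophil RNA or RNA quality.

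Lists of maturing myeloid and red cells were called lower as well. Of 16 myeloid progenitor genes none passed over all genes, and 1 rose and 3 fell adjusted over the list alone (median -0.42, adjusted p 2.80e-04, estimated-correlation adjusted p 0.251). Csf2rb, a cytokine receptor subunit, stood at -1.91 (adjusted p 0.0713). Of 20 erythroid genes none passed, and 4 fell adjusted over the list alone (median -0.29, adjusted p 6.12e-05, estimated-correlation adjusted p 0.187), with the transcription factor gene Gata1 at -1.19 (adjusted p 0.0641). Heme and iron genes had no call and 1 fall adjusted over the list alone (20 tested, median -0.15, adjusted p 0.0133, estimated-correlation adjusted p 0.544). Nuclear genes of oxidative phosphorylation had no member past the threshold either way, but 30 of 32 were negative (median -0.27, adjusted p 2.59e-06, estimated-correlation adjusted p 0.319).

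Lists of neutrophil and macrophage transcripts were tested in the same comparison. None of 9 neutrophil genes passed, and all were negative (median -2.02, adjusted p 7.01e-05, estimated-correlation adjusted p 0.252), with S100a8 at -3.19 ± 1.18. Its intensity varied between arrays of 1 group, from 508 to 1940 in young and from 24.1 to 322 in old HSC. Of 11 macrophage genes 1 fell, Vcam1 (-2.19 ± 0.453), and 6 fell adjusted over the list alone (median -0.56, adjusted p 1.28e-06, estimated-correlation adjusted p 0.0743). Vcam1 lost its call in each leave-one-out fit but the one without young replicate 1 (-2.84 to -1.86).

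The remaining lists had no call as a set in old against young. Of 15 lymphoid-primed genes 1 rose, Id2 (1.504 ± 0.269), which lost its call in each leave-one-out fit but the one without old replicate 2 (1.35 to 1.63), and 2 rose and 3 fell adjusted over the list alone (adjusted p 0.700). Of 21 chromatin regulators Ezh1 rose (1.19 ± 0.249) and Dnmt3b (-0.95 ± 0.201) and Tet1 (-1.04 ± 0.222) fell, with 1 rise and 3 falls adjusted over the list alone (adjusted p 0.148). These 3 calls were lost in each leave-one-out fit, with log2 changes of 1.04 to 1.27 for Ezh1 and of -1.17 to -0.88 for Dnmt3b and Tet1. Integrated stress response genes had 2 rises and 2 falls adjusted over the list alone and none over all genes (adjusted p 0.391). Lists of B lineage, mitochondrial DNA maintenance, mitochondrial chaperones, glycolysis, fatty acid oxidation, cholesterol synthesis, autophagy, antioxidant, interferon, mature B, T and NK, mast and stroma genes had adjusted p between 0.103 and 0.791, and 1 stroma gene fell adjusted over the list alone. Kit (0.38, adjusted p 0.9996), Flt3 (-0.71, adjusted p 0.212), Cd34 (-0.97, adjusted p 0.166), Polg (-0.06, adjusted p 0.9996) and Xist (-0.05, adjusted p 0.9996) did not pass. Camera called 13 lists, 5 higher and 8 lower, and fry called 7.

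Mutator and mid-aged wild-type HSC, both of 32 weeks, were compared to find the effect of mitochondrial DNA mutations. No gene passed the threshold with limma, and 977 of 13492 had an unadjusted p under 0.05 where 674.6 are expected by chance. The values of smallest p are therefore given without a call. Ms4a6c (chromosome 19), a membrane protein gene of myeloid cells, was at 311 ± 117 in mutator and 90.1 ± 26.0 in wild-type HSC (log2 change 1.59 ± 0.262, n = 3 and 3, adjusted p 0.524). Ffar2 (chromosome 7), a receptor for short-chain fatty acids, was at 658 ± 263 and 159 ± 66.0 (1.92 ± 0.358, adjusted p 0.524). Scd1 (chromosome 19), a fatty acid desaturase gene, was at 35.6 ± 8.29 and 160.5 ± 83.8 (-1.66 ± 0.314, adjusted p 0.524).

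Further values of small p were Hddc3 (1.03 ± 0.196), Trim25 (0.74 ± 0.143), Mtmr12 (0.83 ± 0.181), Ap1s2 (-1.25 ± 0.211), Plxna3 (-0.85 ± 0.165), Sult1a1 (-0.70 ± 0.140) and Gpn2 (-0.77 ± 0.154), with adjusted p between 0.524 and 0.567. For the mutated gene Polg the log2 change was -0.47 ± 0.204 (adjusted p 0.668), and its probe sets ranged from -0.50 to 0.39. Slamf1 (-0.04 ± 0.205), Kit (0.55 ± 0.328), Cd34 (0.30 ± 0.277) and Flt3 (0.41 ± 0.220) had adjusted p of 0.747 or more, and so did Xist (3.02 ± 1.67, adjusted p 0.761). The arrays of both groups did not overlap for 6.03% of genes, against 10% by chance.

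The count of 0 depended on the wild-type arrays. Without wild-type replicate 2 it was 220, 209 higher and 11 lower, and without replicate 3 it was 1. It was also 1 with the hybridisation controls as a block and 1 without the pair of arrays with high controls, and it stayed at 0 in the other 4 leave-one-out fits. In simulated data 39.9% of calls here were unchanged genes with the typical group spread, and 59.2% with the SD of each gene. The former had 74.4 such calls per run, the arrays 0, so the shares may not hold here.

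Interferon response genes were the 1 list called in mutator HSC. Of 18 tested members none passed over all genes, 3 rose adjusted over the list alone and 15 were positive (median 0.40, adjusted p 1.75e-04). The call did not hold with an estimated correlation (adjusted p 0.973), and the list had an adjusted p of 0.939 with fry. Rsad2 (0.81 ± 0.197) and Rtp4 (1.12 ± 0.272) had adjusted p of 0.567 over all genes. Without mutator replicate 3 the median was 0.23 and the adjusted p 0.0892, and in the other alternatives with the preset correlation the adjusted p lay between 1.05e-07 and 0.0110. Without wild-type replicate 1 or 3 the number of lists called was 2.

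Lists closest to the mitochondrial defect showed no call. Of 32 nuclear genes of oxidative phosphorylation 14 were positive (median -0.04, adjusted p 0.811). The integrated stress response, which mitochondrial damage induces in other tissues, had 12 of 28 positive (median -0.03, adjusted p 0.925). Mitochondrial chaperones and proteases (15 tested, median 0.18, adjusted p 0.811) and genes that maintain mitochondrial DNA (20 tested, median 0.08, adjusted p 0.900) had no member past the threshold. Among their members Hspa9 was at 0.59 ± 0.180 and Tfam at 0.58 ± 0.218 (adjusted p 0.607 and 0.625). The mitochondrially encoded ND5 was at -0.12 ± 0.307 (adjusted p 0.973).

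In other lists, cholesterol synthesis genes had the lowest adjusted p (0.0768; 5 of 17 positive, median -0.09), with Hmgcs1 at -0.63 ± 0.186. The list of genes known to rise in aged HSC was at a median of -0.06 with 14 of 37 positive (adjusted p 0.605), and 1 member fell adjusted over the list alone. Adjusted over the list alone, 1 glycolysis gene rose and 1 stroma gene fell (adjusted p of the lists 0.925 and 0.903). HSC identity, lymphoid-primed, B lineage, myeloid, megakaryocyte, erythroid, heme, cell-cycle, p53, fatty acid oxidation, autophagy, antioxidant, immediate early, DNA repair, chromatin, neutrophil, macrophage, mature B, T and NK and mast cell genes had no member past the threshold either way and adjusted p between 0.605 and 0.949. Median, mean and test differed in sign for the myeloid, antioxidant, DNA repair, T and NK, mast and stroma lists. Mitochondrially encoded and sex-linked genes had 1 tested member each, too few for a set test.

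The mutator effect was then tested against the age effect. Sult1a1 rose with age and stood at -0.70 in mutator against mid-aged wild-type HSC without a call (adjusted p 0.559), a difference of effects of -3.51 ± 0.198 log2 units (n = 3 in each of 4 groups, adjusted p 1.52e-05). For Ctse the difference was -3.52 ± 0.348 (adjusted p 0.00107), and for Sbspon, at background in young HSC, it was -5.08 ± 0.625 (adjusted p 0.00372), a size that depends on the pseudocount. Plac8, which fell with age, had a difference of 3.99 ± 0.539 (adjusted p 0.00668). Each of these 4 calls held with any array left out.

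In all, 70 genes had different effects, 8 with a higher and 62 with a lower mutator effect. Of 100 array splits, the real one included, 6 gave at least 70 genes (up to 318). Some may keep young and old apart, so they cannot test this count or its parts for chance. Others were Tdrd9 (-4.05 ± 0.454), Scd1 (-3.75 ± 0.444), Tm4sf1 (-3.28 ± 0.299), Gpr183 (-3.26 ± 0.439), Nupr1 (-3.18 ± 0.313), Selp (-2.75 ± 0.368), Ms4a6c (2.75 ± 0.370) and Ncf1 (1.98 ± 0.221), which also held in every leave-one-out fit. Eya4 (-3.53 ± 0.588), Clu (-3.39 ± 0.613), Tyrobp (1.60 ± 0.267), Cd86 (1.52 ± 0.271), Pank1 (1.33 ± 0.240), Ercc6l (1.29 ± 0.239) and Asf1b (1.18 ± 0.223) passed with all arrays and lost their calls without mutator replicate 2 and without each young or old array, except Cd86 without old replicate 2, with values between -4.02 and -2.78 for Eya4 and Clu and between 0.57 and 1.76 for the rest. The count of 70 was 24 without old replicate 1, between 33 and 36 without any other young or old array, 44 without mutator replicate 2, 148 without wild-type replicate 1 and 141 without wild-type replicate 2 (70 higher, 71 lower). It was 39 with young replicates 2 and 3 counted as 1, 157 with the hybridisation controls as a block, 164 without the pair of arrays with high controls and 482 with array weights. Slamf1 (-1.10 ± 0.290, adjusted p 0.188), Flt3 (1.12 ± 0.311, adjusted p 0.235), Cd34 (1.26, adjusted p 0.316), Kit (0.17, adjusted p 0.999) and Polg (-0.42 ± 0.289, adjusted p 0.890) did not pass.

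Of the 180 genes called with age, chosen for a large age effect, 60 of 145 raised and 7 of 35 lowered had a different mutator effect. A further 3 differed without a call for age. The median mutator change was -0.03 for the raised genes (age 1.4995) and 0.10 for the lowered genes (age -1.23).

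As a set, genes known to rise in aged HSC had lower mutator effects than age effects. The contrast contains the age effect, for which the list may rest in part on these arrays, so its call is not independent evidence. Mutator against mid-aged wild type had no call (adjusted p 0.605). Of 37 tested, 15 were lower over all genes and 31 adjusted over the list alone, and none was higher (median -1.84, adjusted p 2.55e-52). This was the 1 list of 14 called whose call held with an estimated correlation (adjusted p 0.0102). Lower differences of effects were also called for HSC identity genes (0 members over all genes, 1 higher and 5 lower adjusted over the list alone, adjusted p 0.00414, estimated-correlation adjusted p 0.435), which lost the call without wild-type replicate 2 (median -0.06). Megakaryocyte genes had 2 lower members, Selp and Clec1b (-1.36 ± 0.233), and 5 adjusted over the list alone (adjusted p 0.00309, estimated-correlation adjusted p 0.211). Among p53 targets 1 was lower, Plk2 (-3.07 ± 0.467; adjusted p 0.0353, estimated-correlation adjusted p 0.435), and cholesterol genes had no member past the threshold (adjusted p 0.0250, estimated-correlation adjusted p 0.582). Calls were lost for Clec1b without mutator replicate 2 or 3 or any young or old array (-1.498 to -1.24), for Plk2 without old replicate 1 or 2 or young replicate 3 (-3.44 to -2.82), for p53 targets without any mid-aged array, old replicate 1 or 2 or young replicate 3 (median -0.38 to -0.09), and for cholesterol genes without young replicate 2 or 3, mutator replicate 2 or wild-type replicate 1 or 2 (median -0.38 to -0.14).

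Higher differences of effects, mutator minus age, were called for 9 lists, with no member past the threshold over all genes. Cell-cycle genes had the lowest adjusted p among them, with 27 of 29 positive, 5 higher and 1 lower adjusted over the list alone (median 0.95, adjusted p 1.11e-10, estimated-correlation adjusted p 0.211). In mutator against mid-aged wild-type HSC this list had no call (15 of 29 positive, adjusted p 0.900), and its change from young to old cannot be told apart from neutrophil RNA or RNA quality. Macrophage genes had 4 higher members adjusted over the list alone (median 0.67, adjusted p 1.46e-05, estimated-correlation adjusted p 0.211). Neutrophil genes (median 2.30, adjusted p 0.00127, estimated-correlation adjusted p 0.437) and erythroid genes (median 0.30, adjusted p 0.00366, estimated-correlation adjusted p 0.435) followed. Oxidative phosphorylation genes were positive for 26 of 32 (median 0.26, adjusted p 0.00629, estimated-correlation adjusted p 0.596), and interferon genes for 15 of 18 (median 0.39, adjusted p 0.0103, estimated-correlation adjusted p 0.582). Myeloid, DNA repair and chromatin genes had medians of 0.29, 0.22 and 0.11 (adjusted p 0.0352, 0.0278 and 0.0352) and estimated-correlation adjusted p of 0.582, 0.302 and 0.489. Without mutator replicate 2 calls were lost for interferon, myeloid, DNA repair and chromatin genes (8 lists then called), and without wild-type replicate 1 for interferon, myeloid and chromatin genes (9 lists). Oxidative phosphorylation lost its call without mutator replicate 3 or wild-type replicate 3, interferon and DNA repair also without old replicate 1, and DNA repair and chromatin also without wild-type replicate 3. Medians in these fits lay between 0.0688 and 0.53. Further losses were interferon and myeloid without mutator replicate 3, myeloid without old replicate 2, young replicate 3 or wild-type replicate 2, and chromatin without old replicate 1 or 3, young replicate 2 or 3 or mutator replicate 1. In the 15 tested lists without a call adjusted p lay between 0.0695 (heme and iron) and 0.921.

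No relation between the effects of age and of the mutator allele was found across genes. Over the 13492 genes Pearson's r was 0.0237, with a leave-one-out standard error of 0.0841, and Spearman's rho was 0.0655. Genes are not independent replicates. Over the 180 genes called with age, r was -0.194 and rho was -0.108, and 74 had the same sign in both. Of 649 genes raised with age in a fit of the young and old arrays alone, 344 had a positive change in mutator HSC (median 0.02, camera p 0.681, adjusted p 0.954). Of 375 genes lowered with age 182 had a positive change (median -0.00613, camera p 0.954). Without wild-type replicate 1 the median of the raised set was -0.119 with a p of 0.0436, the lowest of its alternatives, whose other p lay between 0.0983 and 0.972. The median of the lowered set was negative while its mean (0.0267) and the direction of camera were positive.

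Along the direction from young (0) to old (1), mutator arrays lay at 0.178 ± 0.0328 (SD) and mid-aged wild-type arrays at 0.179 ± 0.0783. The difference was -6.13e-04, with a two-sided exact permutation p of 1 (n = 3 and 3, smallest possible 0.1).

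**Figure D3:**
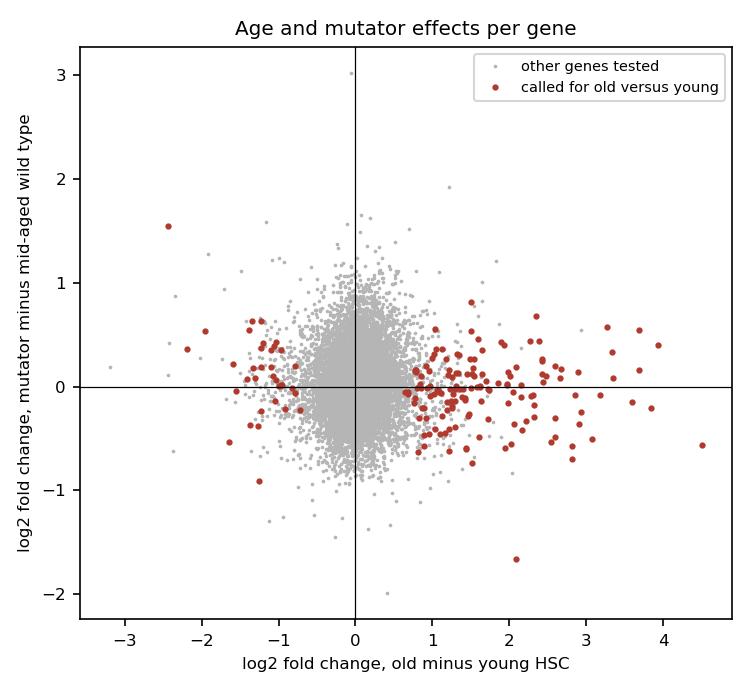
Log2 fold change from young to old HSC (x axis) against log2 fold change from mid-aged wild-type to mutator HSC (y axis), 1 dot per gene of 13492. Red dots are the 180 genes called with age, with an SD of 1.38 along the x axis and 0.358 along the y axis, where all genes have an SD of 0.308 (r = -0.194 over the 180).

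Mid-aged wild-type HSC were set against young and old HSC to place them between the ages. Ctse was at 4565.5 ± 1473 in mid-aged wild-type and 340.0 ± 17.7 in young HSC (log2 change 3.63 ± 0.246, n = 3 and 3, adjusted p 3.91e-05). Cxcr4 was higher by 2.49 ± 0.395 and Nupr1 by 2.20 ± 0.222, while Kit (-1.69 ± 0.328, adjusted p 0.00404) and Cd34 (-1.69 ± 0.277, adjusted p 0.00177) were lower than in young HSC. Against the mid-aged arrays old HSC had more Enpp5 (chromosome 17; 3.72 ± 0.223, adjusted p 1.23e-05), Tdrd9 (3.56 ± 0.321), Sbspon (3.19 ± 0.442), Kit (2.07 ± 0.328) and Slamf1 (0.67 ± 0.205, adjusted p 0.0295). The mid-aged arrays differ from young and old arrays in labelling controls and in actin 3 prime to 5 prime ratio, so here batch and age cannot be told apart.

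The counts were large in both comparisons. Mid-aged wild-type HSC differed from young in 3269 genes, 879 higher and 2390 lower, and old differed from mid-aged in 4004 genes, 2848 higher and 1156 lower. Arrays did not overlap for 38.3% and 42.4% of genes, where chance gives 10%. With quantile normalization the splits were 1280 to 1791 and 2208 to 1609, and median centring moved the median of all genes from -0.04 to -0.12 in the former and from 0.03 to 0.12 in the latter. The former count was 2055 without young replicate 2 and 2071 without replicate 3. Large changes against young included Mid1 (2.95 ± 0.574), Meg3 (2.90 ± 0.681) and Dvl1 (2.47 ± 0.167) upward and Rnf145 (-3.08 ± 0.395), Hmgb3 (-2.93 ± 0.387) and the mismatch repair gene Msh6 (-2.88 ± 0.486) downward. Against old HSC, Meg3 (-2.83 ± 0.681) and Elob (-2.71 ± 0.170) were among the genes lower in old. In simulated data with the typical spread of each group 17.2% and 15.1% of calls in these comparisons were unchanged genes, and 41.1% and 45.6% with the SD of each gene in each group taken as true. Some named genes had another probe set called the opposite way, Ccnd2 and Gclc against young and Rictor, Gclm, Gclc and Dnmt1 against old.

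Gene lists were also compared between mid-aged wild-type and other HSC. Against young, camera called 0 lists (adjusted p 0.0511 to 0.961) and fry called 10. Camera called 2 to 6 lists without any 1 of the young arrays or without wild-type replicate 1. Among members, 8 of 17 cholesterol synthesis genes fell and none rose, with 9 falls adjusted over the list alone (Insig1 -1.57 ± 0.298, Idi1 -1.31 ± 0.290). Of 14 autophagy genes 7 fell and none rose (8 adjusted over the list alone), of 15 mitochondrial chaperones 8 fell and 1 rose over all genes and over the list alone, and of 18 interferon genes 7 fell and none rose (11 adjusted over the list alone; Rsad2 -1.16 ± 0.197, Rtp4 -1.15 ± 0.272). Among HSC identity genes 1 rose and 8 fell, with 2 and 11 adjusted over the list alone. Of the genes known to rise in aged HSC 8 rose and 2 fell, as they did adjusted over the list alone, Sult1a1 (1.26 ± 0.140) and Selp (1.53 ± 0.260) among the former. Median, mean and test differed in sign for the myeloid, oxidative phosphorylation and p53 lists.

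Between old and mid-aged wild-type HSC 11 lists were called, 8 higher and 3 lower in old, and none held with an estimated correlation (adjusted p 0.548 or more). Genes known to rise in aged HSC rose in 29 of 37 and fell in none (33 adjusted over the list alone, adjusted p 2.88e-12, estimated-correlation adjusted p 0.548). HSC identity genes rose in 14 of 24 and fell in 1, with 17 and 1 adjusted over the list alone (adjusted p 4.49e-04, estimated-correlation adjusted p 0.548), and megakaryocyte genes rose in 8 of 18 and fell in none, with 11 and 1 adjusted over the list alone (adjusted p 0.0291, estimated-correlation adjusted p 0.548). Cholesterol, autophagy, fatty acid oxidation and interferon genes rose in 8 members each and fell in none, with 9, 8, 8 and 9 rises adjusted over the list alone (adjusted p 0.0435, 0.0435, 0.0435 and 0.0291), and glycolysis genes rose in 6 and fell in 1, as over the list alone (adjusted p 0.0437). These 5 lists had an estimated-correlation adjusted p of 0.621. Lower in old were cell-cycle genes (2 rises, 6 falls, the same adjusted over the list alone, adjusted p 0.0435), myeloid genes (0 and 3, none adjusted over the list alone, adjusted p 0.0433) and B lineage genes (0 and 1, none adjusted over the list alone, adjusted p 0.0463), again with an estimated-correlation adjusted p of 0.621. Calls were lost for cell-cycle, myeloid and B lineage lists without old replicate 2 (8 lists then called), for cholesterol, fatty acid oxidation, glycolysis, interferon and B lineage lists without wild-type replicate 1 (8 lists), and for megakaryocyte, glycolysis and cell-cycle lists without wild-type replicate 2 (8 lists). They were also lost for cholesterol, myeloid and B lineage lists without wild-type replicate 3 and for fatty acid oxidation, glycolysis and cell-cycle lists without old replicate 1 (9 lists each). The other 18 lists had adjusted p between 0.0610 and 0.984, and median, mean and test differed in sign for heme, oxidative phosphorylation, integrated stress response, immediate early, DNA repair and macrophage genes.

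Mutator HSC were also set against young and old HSC, where age and labelling cannot be told apart. Genotype differs too (0 genes called against mid-aged wild type). Against young HSC Ctse was higher by 3.79 ± 0.246 (n = 3 and 3, adjusted p 7.10e-05), Cxcr4 by 2.82 ± 0.395 (adjusted p 0.00137) and the stress kinase homologue Trib3 by 2.07 ± 0.203 (adjusted p 2.43e-04). Kit (-1.14 ± 0.328, adjusted p 0.0357) and Cd34 (-1.39 ± 0.277, adjusted p 0.00701) were lower. Against old HSC mutator HSC had less Enpp5 (-3.80 ± 0.223, adjusted p 1.27e-05), Sult1a1 (-2.25 ± 0.140), Slamf1 (-0.70 ± 0.205) and Kit (-1.52 ± 0.328), and more Flt3 (1.04 ± 0.220, adjusted p 0.00638), Csf2rb (2.71 ± 0.452) and Cdca8 (2.36 ± 0.278).

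There were 2315 genes past the threshold against young (608 higher, 1707 lower) and 3094 against old (855 higher, 2239 lower), with no overlap between arrays for 41.4% and 46.3% of genes against 10% by chance. With quantile normalization these splits were 926 to 1241 and 1226 to 1782, and median centring moved the median of all genes from -0.05 to -0.12 and from -0.05 to -0.13. The count against young lay between 1148 and 1416 without any 1 of the 3 young arrays or of mutator replicates 1 and 2, and that against old was 1898 without old replicate 1 and 1971 without old replicate 3. Array weights gave 6618 and 6646. Further large changes against young were Meg3 (3.74 ± 0.681), Mid1 (3.52 ± 0.574) and Malat1 (2.17 ± 0.322) upward and Rnf145 (-3.11 ± 0.395) and Pdia3 (-2.68 ± 0.446) downward, and against old Elob (2.36 ± 0.170) upward and Tdrd9 (-3.77 ± 0.321), Sdc4 (-3.36 ± 0.211) and Tm4sf1 (-3.19 ± 0.212) downward. Polg passed in both (-0.69 ± 0.204 and -0.63 ± 0.204) but was at 0.0922 and 0.215 with the mean of its probe sets. Other probe sets were called the opposite way for Prdm16, Urod, Ccnd2 and Phb2 against young and for Nrf1, Gclc, Dnmt1 and H2-Aa against old.

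Against young HSC 4 lists were called and none held with an estimated correlation (adjusted p 0.961 for each). Cholesterol synthesis genes fell in 8 of 17 and rose in 1 (10 and 1 adjusted over the list alone, adjusted p 0.00219). Genes known to rise in aged HSC rose in 7 and fell in 2 of 37 (8 and 2 adjusted over the list alone, adjusted p 0.0460), immediate early genes rose in 1 of 23 (0 adjusted over the list alone, adjusted p 0.0302) and mature B genes in 2 of 5 (3 adjusted over the list alone, adjusted p 0.0460). The last 3 lists each lost their call without mutator replicate 2, where 1 list was called, and 2 lists were called without mutator replicate 3, young replicate 2 or young replicate 3. The list of genes known to rise in aged HSC also lost its call without young replicate 1. The other 25 lists had adjusted p between 0.0868 and 0.968, and median, mean and test differed in sign for lymphoid-primed, myeloid, mitochondrial DNA maintenance, integrated stress response, p53, neutrophil and stroma genes.

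Against old HSC 10 lists were called, 6 lower and 4 higher in mutator HSC, and none held with an estimated correlation. Genes known to rise in aged HSC fell in 29 of 37 and rose in none (32 adjusted over the list alone, adjusted p 2.27e-15, estimated-correlation adjusted p 0.372). HSC identity genes fell in 12 and rose in 1 of 24 (13 and 1 adjusted over the list alone, adjusted p 0.00107), and megakaryocyte genes fell in 8 of 18 and rose in none (8 and 1 adjusted over the list alone, adjusted p 0.0160), each with an estimated-correlation adjusted p of 0.597. Cholesterol genes fell in 8 of 17 (13 with 1 rise adjusted over the list alone, adjusted p 0.00107), glycolysis genes in 6 of 14 (7 adjusted over the list alone, adjusted p 0.0376) and autophagy genes in 7 of 14, as over the list alone (adjusted p 0.0394). Cell-cycle genes rose in 6 and fell in 2 of 29, as over the list alone (adjusted p 0.0160), myeloid genes rose in 1 of 16, as over the list alone (adjusted p 0.0376), and neutrophil (adjusted p 0.0212) and B lineage genes (adjusted p 0.0464) had no member past the threshold. These 7 lists had an estimated-correlation adjusted p of 0.627. Calls were lost for autophagy and glycolysis without mutator replicate 1, for B lineage without mutator replicate 1 or old replicate 2, and for myeloid and neutrophil genes without mutator replicate 2 or old replicate 2, with 7 or 8 lists called in these fits. The other 19 lists had adjusted p between 0.0965 and 0.979, and median, mean and test differed in sign for lymphoid-primed, heme, oxidative phosphorylation, mitochondrial DNA maintenance, integrated stress response, immediate early, DNA repair, chromatin and macrophage genes.

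Ly6D-positive and Ly6D-negative CLP were compared for the step at which lymphoid progenitors turn to the B lineage. Vpreb1 (chromosome 16), a chain of the surrogate light chain of the pre-B cell receptor, rose from 82.7 ± 48.1 to 5602 ± 685 (log2 change 5.92 ± 0.380, n = 2 and 2, adjusted p 1.53e-06), and its partner Igll1 (chromosome 16) rose by 5.91 ± 0.280 (adjusted p 8.82e-08). The B cell transcription factor gene Ebf1 (chromosome 11) rose by 4.29 ± 0.234 (adjusted p 3.95e-07), the recombinase gene Rag1 by 3.92 ± 0.133 (adjusted p 1.89e-09) and the sort marker Ly6d (chromosome 15) by 4.76 ± 0.302 (adjusted p 1.49e-06). Ccr9, a homing receptor of thymus progenitors, fell from 1208 ± 223 to 188 ± 144 (-2.78 ± 0.342, adjusted p 4.73e-04). Ptger3, a prostaglandin receptor gene, fell by 3.67 on the log2 scale (SE 0.445), and the granule protease gene Prtn3 by 2.69 (SE 0.382).

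In all, 384 of 14343 genes passed, 214 higher and 170 lower in Ly6D-positive CLP. The arrays did not overlap for 35.3% of genes, against 33.3% by chance for 2 against 2. Further increases were Pou2af1 (5.64 ± 0.146) and Gpat3 (4.62 ± 0.283), both from background (4.22 and 3.19 with a pseudocount of 64), Chchd10 (4.07 ± 0.364), Gimap4 (3.93 ± 0.793) and Prkcb (3.61 ± 0.456), and further decreases were Ddx4 (-3.22 ± 0.297), Wfdc17 (-3.09 ± 0.376) and Hsd3b7 (-2.70 ± 0.291). Gimap4 lost its call without Ly6D-positive replicate 2 or Ly6D-negative replicate 2 (2.65 to 5.20 with 1 array left out). Il7r (0.56 ± 0.223, adjusted p 0.279), Flt3 (-0.22 ± 0.258, adjusted p 0.845), Kit (-0.86 ± 0.389, adjusted p 0.367), Cd34 (-1.34 ± 0.356, adjusted p 0.0716) and Polg (-0.46 ± 0.280, adjusted p 0.562) did not pass. In simulated data with the typical measured spread of each group 43.7% of calls here were unchanged genes, and 79.6% with the SD of each gene in each group taken as true. The count was 105 with array weights, where Vpreb1, Igll1, Pou2af1, Ly6d, Ebf1, Rag1, Ptger3, Ccr9 and Prtn3 still passed, and 752 without Ly6D-negative replicate 1. It was 0 when limma fitted the 4 CLP arrays alone, with 957 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.0581.

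B lineage genes rose as a group. Of 21 tested 15 rose and none fell, and 19 rose and 1 fell adjusted over the list alone (median 1.998, adjusted p 8.28e-44), a call that held with an estimated correlation (adjusted p 0.00113). HSC identity genes fell in 3 of 24 and rose in none (5 and 1 adjusted over the list alone, median -0.57, adjusted p 3.28e-05, estimated-correlation adjusted p 0.0715). The 3 were Hoxa9 (-1.57 ± 0.274), Lmo2 (-1.36 ± 0.314) and Gata2 (-1.03 ± 0.227). Lmo2 lost its call in all 4 fits that left out 1 CLP array (-1.52 to -1.20) and Gata2 in each but the one without Ly6D-negative replicate 1 (-1.17 to -0.90). Myeloid genes fell in 2 of 17, Prtn3 and Csf3r (-2.11 ± 0.463), and in 3 adjusted over the list alone (median -0.28, adjusted p 0.00709, estimated-correlation adjusted p 0.923). Both the list and Csf3r (-2.95 to -1.27) lost their call without Ly6D-positive replicate 1 or Ly6D-negative replicate 2, where 2 lists were called. Ly6D-negative replicate 2 carries neutrophil transcripts, with S100a8 at 1370.8 against 16.1 to 75.6 in the other CLP arrays and a log2 mean of the neutrophil list of 8.12 against 5.22 to 5.38. Without Ly6D-negative replicate 1, 5 lists were called. Of 19 lymphoid-primed genes 2 rose and 2 fell, with 2 and 3 adjusted over the list alone (adjusted p 0.744), and the other 26 lists tested had adjusted p between 0.163 and 0.987. Median, mean and test differed in sign for lymphoid-primed, megakaryocyte, erythroid, p53, antioxidant and chromatin genes.

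**Figure D4:**
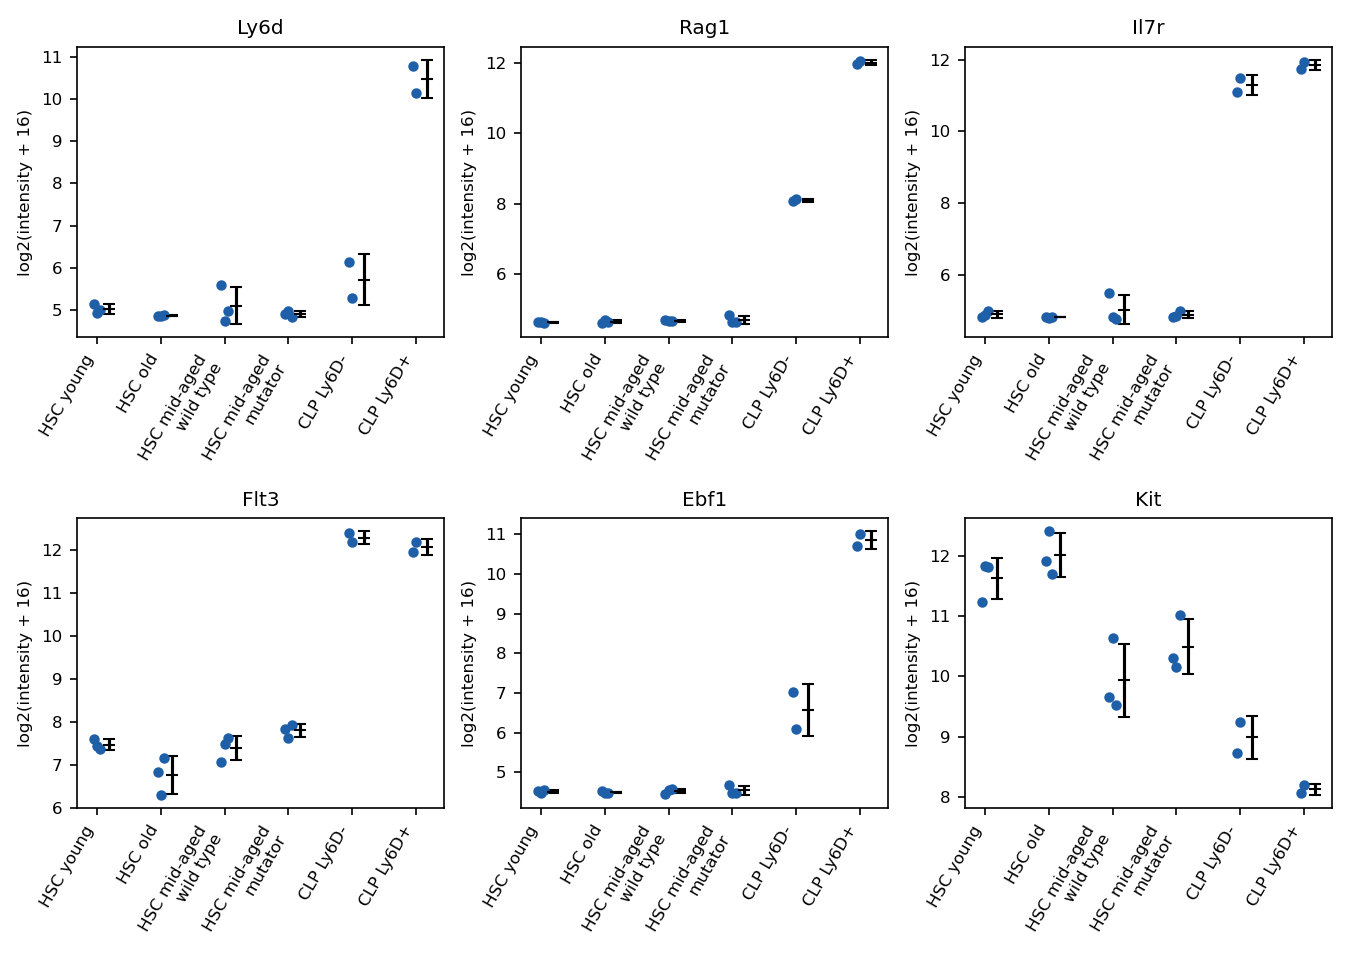
Expression of Ly6d, Rag1, Il7r, Flt3, Ebf1 and Kit in the 4 HSC groups and the 2 CLP groups, as log2(intensity + 16). Dots are arrays and bars the mean ± SD, and Ly6d, Ebf1 and Rag1 are higher in Ly6D-positive than in Ly6D-negative CLP while Il7r and Flt3 are high in both.

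CLP of both kinds were compared with young HSC for the change from stem cell to lymphoid progenitor. Dntt (chromosome 19), the DNA polymerase that adds untemplated nucleotides to antigen receptor genes, rose from 21.7 ± 1.61 (n = 3) to 8738 ± 107 (n = 4), a log2 change of 7.86 ± 0.222 (adjusted p 5.07e-11). Il7r (chromosome 15) rose by 6.67 ± 0.170 (adjusted p 2.38e-11), Irf8 by 5.72 ± 0.366 (adjusted p 1.09e-07) and the cytokine receptor gene Flt3 by 4.71 ± 0.197 (adjusted p 1.80e-09). Mecom (chromosome 3), a transcription factor gene needed by HSC, fell from 2509.9 ± 411 to 44.5 ± 66.6 (-5.88 ± 0.408, adjusted p 2.34e-07). Procr fell by 5.43 on the log2 scale (SE 0.172, adjusted p 1.35e-10), Kit by 3.07 (SE 0.297) and Slamf1 by 2.81 (SE 0.188).

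Of 14343 genes 4404 passed, 1798 higher and 2606 lower in CLP, and the arrays did not overlap for 40.1% of genes where chance gives 5.71% for 4 against 3. Rag1 (5.43 ± 0.101), Atp8b4 (5.64 ± 0.205), Blnk (5.39 ± 0.176) and Ptger2 (5.09 ± 0.119) were among the largest increases, and Ly6d rose by 3.07 ± 0.231. Tgm2 (-6.91 ± 0.157), Myct1 (-5.94 ± 0.372), Aldh1a1 (-5.79 ± 0.222) and Slc18a2 (-5.33 ± 0.235) were among the largest decreases. Xist fell to background by 7.78 on the log2 scale (SE 1.46; 6.34 with a pseudocount of 64). Il7r, Rag1, Ptger2 and Ly6d in young HSC and Tgm2, Aldh1a1 and Slc18a2 in CLP were at background as well, so these sizes depend on the pseudocount. The Y-linked signal and the spiked controls also set the CLP arrays apart from the young HSC arrays. The 6 mid-aged HSC arrays, with a log2 LysX level of 12.5 to 13.8 near the 12.5 to 13.0 of the CLP arrays, had Il7r at 11 to 28.8 and Flt3 at 119.2 to 229.5, against 2162.1 to 3929.8 and 3928.7 to 5380.6 in CLP. Their mean over the lymphoid-primed list was 6.79 to 7.14 on the log2 scale, against 9.94 to 10.2 in CLP. Mid-aged wild-type replicate 3, which carries Y-linked signal, had Il7r at 11 and Flt3 at 181.7. For the rest sex and labelling were not separated from cell type. Cd34 (0.62 ± 0.272, adjusted p 0.107) did not pass, Polg rose by 0.74 ± 0.214 (adjusted p 0.0189) with probe sets between 0.01 and 0.74, and ND5 rose by 0.95 (adjusted p 0.0167). Named genes with another probe set called the opposite way were Prdm16, Hspe1, Map1lc3b and Nfkbia.

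The 4 lists with calls that held with an estimated correlation describe cell identity. HSC identity genes fell in 23 of 24 and rose in none (23 and 1 adjusted over the list alone, median -3.18, adjusted p 4.01e-21, estimated-correlation adjusted p 3.21e-04), Gata2 (-4.79 ± 0.173) among them. Lymphoid-primed genes rose in 16 of 19 and fell in 2, as over the list alone (median 3.46, adjusted p 7.33e-16, estimated-correlation adjusted p 1.16e-04). B lineage genes rose in 17 of 21 and fell in none (19 adjusted over the list alone, median 2.44, adjusted p 9.07e-20, estimated-correlation adjusted p 0.00926). Megakaryocyte genes fell in 11 of 18 and rose in none (13 and 1 adjusted over the list alone, median -1.42, adjusted p 3.97e-07, estimated-correlation adjusted p 0.0114), with Vwf (-4.70 ± 0.447) and Pf4 (-3.71 ± 0.264) as examples.

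Further lists were called in CLP against young HSC without holding under an estimated correlation. Genes known to rise in aged HSC fell in 25 of 37 and rose in none (26 adjusted over the list alone, adjusted p 6.87e-12, estimated-correlation adjusted p 0.0873). Erythroid genes fell in 10 and rose in 1 of 20 and antioxidant genes fell in 9 of 17, both as over the list alone (adjusted p 0.00171 and 0.00182, estimated-correlation adjusted p 0.193 for each). Cholesterol genes fell in 9 and rose in 1 of 17 (12 and 1 adjusted over the list alone, adjusted p 0.00452, estimated-correlation adjusted p 0.245). Macrophage genes fell in 4 of 11 (adjusted p 0.0114, estimated-correlation adjusted p 0.193) and glycolysis genes in 6 of 14 (adjusted p 0.0274, estimated-correlation adjusted p 0.532), as over the list alone. Myeloid genes rose in 9 and fell in 2 of 17 (adjusted p 0.0111, estimated-correlation adjusted p 0.404) and DNA repair genes rose in 8 and fell in 1 of 17 (adjusted p 0.0111, estimated-correlation adjusted p 0.145), again as over the list alone. Cell-cycle genes rose in 5 and fell in 1 of 29 (2 and 0 adjusted over the list alone, adjusted p 0.0274, estimated-correlation adjusted p 0.683), a call lost without young replicate 1 or Ly6D-negative replicate 1 (medians of the leave-one-out fits 0.25 to 0.54). The glycolysis call was lost without young replicate 1 or Ly6D-positive replicate 2 (medians -0.51 to -0.30). The sex-linked list of 4 genes had 3 rises and 1 fall, as over the list alone (adjusted p 0.245), and the other 16 lists tested had adjusted p between 0.0778 and 0.995. Median, mean and test differed in sign for integrated stress response, p53, immediate early, chromatin and mature B genes.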

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

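The tests of the sex of the animals, of the mid-aged arrays and of the cell-cycle genes were chosen after these results were seen.

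Y-linked signal appeared in 5 arrays that are labelled female, in probe sets that no comparison was about. Eif2s3y was at 551.85 in mid-aged wild-type replicate 3, 695.52 and 423.31 in Ly6D-positive CLP replicates 1 and 2, and 613.89 and 757.85 in Ly6D-negative CLP replicates 1 and 2, against at most 12.7 in the other 11 arrays. Male cells mixed into a female sample are argued against by Xist, whose highest value in these arrays was 0.225% of its mean in the other 11. All 3 named Y-linked genes, Eif2s3y, Kdm5d and Uty, were higher in each of the 5 arrays than in any other, so that male animals are a candidate explanation. An exchange between CLP and HSC arrays is argued against by Il7r, at 2162.1 to 3929.8 in the 4 CLP arrays and 11 to 28.8 in HSC, and one between the Ly6D groups by Ly6d, at 1126 to 1757.5 in Ly6D-positive and 23 to 54.7 in Ly6D-negative CLP. An exchange with a sample from outside the series stays open. No biological explanation was tested, and without genes on X and Y the counts were 0 for mutator against mid-aged wild type, 381 for Ly6D-positive against Ly6D-negative CLP and 4224 for CLP against young HSC.

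Control transcripts added to the RNA before labelling, which no comparison used, separated the 6 mid-aged HSC arrays from the 6 young and old ones. The log2 difference was 2.34 for DapX, 3.68 for LysX, 3.33 for PheX and 3.47 for ThrX, and the 4 controls did not overlap between the arrays. A gradual change with age is argued against as the whole cause of the distance between these arrays, since 99.2% of 1984 genes called both for mid-aged wild type against young and for mutator against old moved the same way, 496 higher and 1473 lower than in both ages. These 2 comparisons share no array. A difference in labelling fits the controls but need not raise the actin ratio, at 2.11 to 3.85 in CLP with similar LysX. A change peculiar to mid age stays open.

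The cell-cycle and neutrophil lists were called lower in old than in young HSC, and neither call held with an estimated correlation (adjusted p 0.0717 and 0.252). The difference of the cell-cycle list mean was -0.823 (SE 0.254) over the 12 HSC arrays and -0.709 (SE 0.310) with the neutrophil list mean as a covariate, with a 95% interval of -1.44 to 0.0246. The neutrophil list was written from general knowledge, none of its genes is in another list, and its abundant members ranged over arrays, as S100a8 from 24.1 to 2455.4 and Ngp from 24.1 to 2433.6 in HSC; the gates of the sort are not given in the sources used here. RNA quality is confounded with age, with a gap of 0.120 between the lowest young and the highest old log2 actin ratio. Neutrophil RNA, RNA quality and an effect of age on the cell cycle therefore cannot be told apart.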

How the results depend on the processing

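Leaving out genes on X and Y, the hybridisation controls as a block, leaving out the 2 mid-aged arrays with high controls and counting young replicates 2 and 3 as 1 were tests chosen after the data were seen. A fit without 1 CLP array leaves 1 array in its group, which is assumed to vary like the other groups. Over named genes 17762 values kept their side of the threshold, 998 were no longer past it, 225 newly passed and 20 reversed without passing. Over gene lists these counts were 2991, 201, 108 and 0. Of the values kept, 73 and 184 without a call changed sign. Except for every probe set, where more values are tested, the cause was not tested for the changes below. Signal over background limits the dim genes, and the filter on them kept 13492 of 18194 genes.

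Counts of genes called moved by more than 1.5 times in these settings. With every probe set there were 6266 for mid-aged wild type against young, 7644 for old against mid-aged wild type, 4738 for mutator against young, 6294 for mutator against old, 730 for Ly6D-positive against Ly6D-negative CLP and 7426 for CLP against young. With array weights there were 1883 for old against young, 482 for the difference of effects, 6618 for mutator against young, 6646 for mutator against old and 105 between the CLP groups. In a fit of only the groups compared there were 1057 for old against young and 0 with limma between the CLP groups, where 957 genes had an unadjusted p under 0.05. With young replicates 2 and 3 as 1 there were 92 for old against young, 39 for the difference of effects, 2058 for mid-aged wild type against young and 1173 for mutator against young. With the hybridisation controls as a block there were 1 for mutator against mid-aged wild type and 157 for the difference, and without the 2 arrays with high controls 1 and 164.

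Leaving out 1 array gave 0 to 220 genes for mutator against mid-aged wild type, 86 to 114 for old against young, 24 to 148 for the difference, 2055 to 4177 for mid-aged wild type against young, 2790 to 4820 for old against mid-aged wild type, 1148 to 2549 for mutator against young, 1898 to 3236 for mutator against old, 281 to 752 between the CLP groups and 3198 to 4413 for CLP against young. The highest counts were without wild-type replicate 2 (220, 4177 and 4820), wild-type replicate 1 (148), young replicate 1 (114), mutator replicate 3 (2549 and 3236) and Ly6D-negative replicate 1 (752 and 4413).

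Lists called with an estimated correlation were 0 for mutator against mid-aged wild type, 1 for old against young, 1 for the difference, 0 for old against mid-aged wild type, 0 for mutator against young, 0 for mutator against old, 1 between the CLP groups and 4 for CLP against young. Fry called 0 for mutator against mid-aged wild type, 7 for old against young, 1 for the difference, 10 for mid-aged wild type against young and 6 for mutator against old. With no filter on dim genes there were 2 for mutator against mid-aged wild type, 10 for mid-aged wild type against young and 8 for mutator against young, and with the mean of all probe sets 8 and 8 for the latter pair. For mid-aged wild type against young there were also 2 with the replicate block and 3 with quantile normalization, which gave 7 for old against mid-aged wild type. Leaving out 1 array gave 0 to 2, 12 to 17, 8 to 16, 0 to 6, 8 to 11, 1 to 5, 7 to 11, 2 to 5 and 11 to 13 lists, in the order of comparisons of the preceding paragraph.

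The medians of the age sets in mutator HSC lie near 0 and changed sign. The lowered set was at 0.00673 with median centring, 0.0199 with no dim filter, 0.0210 with the mean of all probe sets, 0.0260 with every probe set, 0.0108 with array weights, 0.0109 with a pseudocount of 1, 0.0198 without the 2 arrays, 0.0113 with young replicates 2 and 3 as 1, 0.0331 with 100 genes, and -0.0972 to 0.103 with 1 array left out. The raised set was at -0.0352 with array weights, -0.0452 without the 2 arrays, -0.00684 with young replicates 2 and 3 as 1, -0.0482 with 100 genes, and -0.119 (without wild-type replicate 1) to 0.106 (without wild-type replicate 2) with 1 array left out. The correlation of effects was -0.194 over genes called and -0.0372 to 0.0565 with 1 array left out.

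Named genes reversed with the mean of all probe sets. They were Rrm2b (0.0277), Gclm (-0.0900) and Atr (0.0382) for mid-aged wild type against young, and Mcm5 (0.194), Mcm2 (0.0185), Rrm2b (-0.117) and Gclm (0.539) for old against mid-aged wild type. For mutator against young they were Ccnd2 (-0.108), Rrm2b (0.0567), Gclm (-0.0771) and Polg (0.0922), and for mutator against old Rrm2b (0.146), Gclm (-0.526), Parp1 (-0.107) and Polg (0.215). The others were Slc25a36 (0.223) between the CLP groups and Hspe1 (0.184), Map1lc3b (0.0655) and Nfkbia (0.247) for CLP against young. Mcm6 reversed without the 2 arrays with high controls (-0.301, mutator against old).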

Other observations

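The test of the interferon genes was chosen after its result was seen, and the splits of the arrays were planned.

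The intensity of Mki67, a gene of dividing cells, varied between arrays of 1 group. It was at 972.1 in young replicate 1 and at 3265.4 and 3417.7 in young replicates 2 and 3, and old HSC ranged from 612 to 1500.5. In CLP it lay between 2874 and 5157.2. Neutrophil transcripts were high in Ly6D-negative CLP replicate 2, with S100a8 at 1370.8 against 16.1 to 75.6 in the other CLP arrays and Camp at 820.6 against 23.2 to 34.2. Old replicate 1 had S100a8 at 322 against 41.9 and 24.1 in the other old arrays.

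Young replicates 2 and 3 were more alike than any other pair of young or old arrays. The SD of their log2 difference was 0.164, against 0.253 to 0.299 in the other pairs within these groups, and 17 probe sets had identical values, against 16 to 32. Among the mid-aged arrays, mutator replicate 1 and wild-type replicate 1 had log2 hybridisation control levels of 10.9 and 10.8, against 8.09 to 8.87 in the other 4.

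A hypothesis was that mutator HSC show an interferon response. The list median of 0.402 was reached or passed in size by 3 of the 10 splits of the 6 mid-aged arrays, the real one included, with 0.528 as the highest of the other splits. These splits are too few for a share under 0.05, and the hypothesis of an interferon response in mutator HSC stays open.

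Splits of the same arrays into other groups of 3 number 10, too few for a share under 0.05. For mutator against mid-aged wild type 0 genes were called with limma (977 at an unadjusted p under 0.05), a count that each of the 10 splits must reach, and the highest of the others was 1010. At least 1 list was called in 9, with up to 6. The split with 1010 genes sets mutator replicate 1 and wild-type replicates 1 and 3 against the rest, and a split with 441 genes joins mutator replicates 1 and 2 with wild-type replicate 1. Of the 4 splits that keep mutator replicate 1 and wild-type replicate 1, the arrays with high hybridisation controls, together, only these 2 had genes called. They point to a structure of these arrays whose source stays open. With the hybridisation controls as a block 1 gene was called.

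For old against young 1 of 10 splits, the real one, gave 180 genes, with 0 as the highest of the others, and 2 gave 13 lists, with 15 in another split. For mid-aged wild type against young 1 split gave 3269 genes (others 0), and 0 lists were called with camera (others up to 5), which every split must reach. For old against mid-aged wild type 1 split gave 4004 genes (others 0) and 2 gave 11 lists (others up to 12). For mutator against young 1 split gave 2315 genes (others 0) and 4 gave 4 lists (others up to 6), and for mutator against old 1 split gave 3094 genes (others 0) and 2 gave 10 lists (others up to 11).

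For the difference of effects 6 of 100 splits gave at least 70 genes (highest other 318), which cannot test chance. Only the real one gave 14 lists, but 3 others gave 13, too close to tell. The list count was 8 to 16 with 1 array left out, and the 1 list that held with an estimated correlation is not independent evidence. For CLP against young HSC 1 of 35 splits gave 4404 genes (highest other 1922), which argues against chance but not sex or labelling. For lists 4 gave 13 (others up to 14), which chance allows. Of the 10 splits of the mid-aged arrays 9 gave a median of the raised age set as large in size as 0.0204 (highest other 0.301), 9 gave one of the lowered set as large as -0.00613 (highest other 0.2496), and 9 gave a correlation of effects as large as 0.0237 (highest other 0.107).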
